A study of Mus musculus with 33 samples.

How the data were processed

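The series holds 33 mouse samples. RNA-seq of 22 libraries followed MEFs and NPCs on days 0, 2, 4, 8 and 12 of SKM induction (2 libraries per group) beside R1 ESC and SKM iPSC (1 library each), and 6 ChIP-seq samples covered Sox2, Klf4 and H3K27ac in MEFs. The 5 input samples were not used here. Per the labels, reprogramming cells were kept in mouse ES medium with doxycycline and sorted cells were lysed in TRIzol. Groups follow the sample titles, also for NPC days 2 and 4, where another label field gives days 0 and 2. The Klf4 samples carry a Sox2 antibody label and are reported under their titles. The column taken for SKM iPSC carries a 9 in its heading that the labels do not explain, and was matched by elimination.

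Per the submitters' processing notes, reads were handled with CASAVA 1.8.4 and FastQC, RNA-seq reads were aligned with STAR 2.5.1b, ChIP-seq reads with Bowtie2, peaks were called with MACS2, and the build was mm9. The expression values, as deposited, are read counts per gene made by the authors. The design, fixed before the data were examined, assumed FPKM, but the per-sample values are whole-number counts, so the count model planned for that case was used. The authors also deposited log2 fold changes and adjusted p-values of their own comparisons, reported as deposited, with no test named. The deposited peak lists give fold enrichment over background made by MACS2 in the hands of the authors. They also give the authors' -log10 p and -log10 q values per peak.

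The count tables held 37999 lines for 37620 Ensembl genes, with 307 genes listed more than once and kept once. Of the symbols, 27 had been turned into dates and were restored, 16079 genes had no symbol (0.6 to 1.41% of the counts per library) and 73 shared a symbol. Reads of genes with near-identical copies, such as the 2-cell embryo genes, are uncertain. Library totals are given with the results, and a count of 0 was replaced by a floor of 3 counts over the summed libraries of a group where a fold is given as a lower bound.

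Differential expression used edgeR 4.0.16 in R 4.3.3, with TMM scaling, quasi-likelihood fits and Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. Genes needed at least 1 CPM in at least 2 libraries of the fit. A fit per cell type held its 5 groups and the pluripotent lines, and a joint fit gave the starting cells, the day 12 cells and the interactions. These made 16 comparisons: each later day against day 0, day 12 against day 8 and against the lines, for both cell types, MEFs against NPCs on days 0 and 12, and the difference of their responses on days 2 and 12. SE is the size of the log2 fold change over the square root of the F statistic. Levels are CPM with TMM sizes over all 22 libraries.

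Genes were named by a rule fixed before the data were examined: 23 core genes, in each list the 4 members of largest absolute change, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, separate replicates and a proper symbol. The text prints a part of the genes the rule takes, 244 gene and comparison pairs. That part was picked after the values were seen, and genes whose calls were lost with single libraries left out were dropped by preference, so the printed genes are steadier than the rule's genes as a whole. The rule takes 1377 called pairs, of which 942 were called with every single library left out. Some single genes that the rule takes are not reported. Regions named are the 5 per factor of highest fold enrichment in either replicate.

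The 25 gene lists, fixed before the data were examined, were pluripotency, early reprogramming, mesenchymal, epithelial, neural progenitor, neuron, astrocyte, oligodendrocyte, keratinocyte, macrophage, endothelial, skeletal muscle, trophoblast and primitive endoderm, mesendoderm, cell cycle, p53 and senescence, interferon response, TGF-beta, glycolysis, DNA methylation and chromatin, germline, 2-cell embryo, immediate-early, ribosomal protein and mitochondrial. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, in 394 tests, again with an estimated correlation, and with fry. Called members are also counted with adjustment over the list alone.

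Peaks on unplaced sequence were left out. Peaks overlapped when they shared at least 1 bp, and regions of a factor were merged peaks overlapped by both replicates. Overlaps were tested by 1000 circular shifts along each chromosome, 2-sided, with exact 95% intervals, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

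The model was tested on simulated data with 200 genes changed by log2 2. It called 136 of them in MEFs on day 2 with 15 other calls and 149 in NPCs on day 2 with 7 others. The day 2 interaction gave 41 with 3 others and the day 12 groups 134 with 8 others. These rates hold for simulated data only, as real replicate spread differed between groups. With nothing changed 0 genes were called. Simulated peaks with 30% overlap gave 30.1%, and none planted gave 0.25% with a shift p of 0.929.

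Alternatives planned before the data were examined were no filter on low counts, median-of-ratios scaling, quantile normalization, fits of only the groups compared, no trend, a replicate block, a log2 fold change of at least 1, each library left out, camera with an estimated correlation, fry, reciprocal overlap of 50%, -log10 q of at least 5 and the 5000 peaks of lowest p. DESeq2 1.42.0, gene lists with each library left out and lists without NPC day 4 replicate 1 were chosen after seeing the data. Quantile-normalised values were tested with limma on log2 CPM, so this alternative changed the test along with the scaling.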

Results

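Reprogramming with Sox2, Klf4 and Myc (SKM), without an added Oct4 gene, was followed in mouse cells by 2 assays. RNA-seq counted transcripts in 22 libraries. They came from MEFs (mouse embryonic fibroblasts) and NPCs (neural progenitor cells) on days 0, 2, 4, 8 and 12, with 2 libraries per cell type and day, and from 2 pluripotent lines with 1 library each: R1 ESC, an embryonic stem cell line, and SKM iPSC, induced pluripotent stem cells made with the same factors. Day 4 to 12 libraries of MEF origin and day 8 and 12 libraries of NPC origin were labelled GFP, and the series design describes EGFP-positive populations (a green fluorescent reporter). Day and GFP label thus change together, and a fold change of a GFP-labelled group against day 0 is not one of time alone. The labels do not name the gene behind the reporter. OG2, a name that an H3K27ac sample carries, is a mouse line with a Pou5f1 reporter, and a sort on such a reporter would itself set a rise of Pou5f1. ChIP-seq, which sequences the DNA bound by a protein, gave peak lists for Sox2 and Klf4 on day 2 of MEF reprogramming (2 samples each) and for H3K27ac, a histone mark of active promoters and enhancers, on days 0 and 2 (1 sample each). Total counts per MEF library were 19217668 and 19713839 on day 0, 18501539 and 20102260 on day 2, 18444439 and 18807508 on day 4, 18851376 and 15902838 on day 8 and 17178989 and 18226370 on day 12. NPC libraries held 19195363 and 18416667 counts on day 0, 19710478 and 18934371 on day 2, 19421076 and 18859843 on day 4, 20049748 and 16220358 on day 8 and 17164950 and 17380267 on day 12. R1 ESC had 19798488 and SKM iPSC 19115548 counts, the latter from a column matched by elimination. Levels are given in CPM, counts scaled to a common library size, as mean ± SD, and fold changes are log2 values ± SE, from 2 libraries per group unless stated. The labels do not say that replicates came from separate cultures, so each p measures only the spread between these samples, and intervals and floors cover counting error only. The genes named are a part of those that a fixed rule takes, and they were picked after their values were seen, in part because their calls held with single libraries left out. Over all 1377 called pairs of gene and comparison of the rule, 942, or 68.4%, kept their call with every single library left out. Of the 244 fold changes printed, 62 moved by over 1 log2 unit with a single library left out, and the 31 that moved by over 2 are given with that library. Where no counts of the gene were left in the group, as for Pou5f1, Lin28a and Epcam without MEF day 0 replicate 2, the fitted value rests on the prior count of the model.

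The reprogramming factors were examined first, because they check the labels. Their counts add transgene and endogenous transcripts, which the tables do not separate. Sox2 lay at 4.93 ± 1.15 CPM in MEFs on day 0 and at 819 ± 164, 910.4 ± 33.8, 410.3 ± 39.4 and 321 ± 52.8 CPM on days 2, 4, 8 and 12. NPCs, which express Sox2 of their own, had 186 ± 30.4 CPM on day 0, and 668 ± 34.3, 1306 ± 166, 479.7 ± 8.46 and 330.1 ± 53.4 CPM afterwards. Klf4 was at 43.1 ± 2.13 CPM in MEFs and 14.6 ± 9.05 CPM in NPCs before induction, peaked on day 4 at 1324 ± 22.6 and 1726 ± 278 CPM, and was at 416 ± 82.9 and 445 ± 38.04 CPM on day 12. Myc went from 58.8 ± 0.150 to 1564 ± 74.4 CPM by day 4 in MEF-derived cells and from 62.5 ± 7.55 to 1857 ± 256 CPM in NPC-derived cells, with 502 ± 65.9 and 530.1 ± 54.8 CPM on day 12. In the single libraries of R1 ESC and SKM iPSC, Myc was at 9.35 and 2.26 CPM and Sox2 at 519 and 533 CPM. In MEF-derived cells the rise over day 0 was 7.22 ± 0.33 for Sox2, 4.62 ± 0.26 for Klf4 and 4.56 ± 0.26 for Myc on day 2. It was 7.41 ± 0.33, 4.83 ± 0.26 and 4.62 ± 0.26 on day 4, 6.25 ± 0.32, 3.55 ± 0.25 and 3.48 ± 0.24 on day 8, and 5.95 ± 0.31, 3.20 ± 0.24 and 3.03 ± 0.24 on day 12. NPC-derived cells gave 1.84 ± 0.24, 5.94 ± 0.47 and 4.21 ± 0.28 on day 2, 2.83 ± 0.25, 6.90 ± 0.49 and 4.91 ± 0.29 on day 4, and 1.39 ± 0.24, 5.60 ± 0.46 and 3.95 ± 0.28 on day 8. On day 12 Klf4 and Myc were higher by 4.96 ± 0.45 and 3.12 ± 0.27.

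The first 2 days of induction in MEFs showed which genes moved at the start. Fibroblast genes fell. Col1a1, which encodes the main collagen of connective tissue, changed by -4.55 ± 0.60, the surface protein Thy1 by -4.81 ± 0.96, the receptor Pdgfrb by -8.42 ± 0.48, the collagen cross-linking enzyme Lox by -7.45 ± 0.93, and the mesenchymal transcription factors Snai2 and Twist1 by -5.11 ± 0.77 and -3.25 ± 0.46. Targets of TGF-beta, a signal that maintains the fibroblast state, fell with them, with Thbs1 at -10.65 ± 1.15 and Ctgf at -10.75 ± 1.31. Mesenchymal genes had 0 higher and 30 lower of 33 (1 and 30 adjusted over the list alone), camera adjusted p = 1.65e-10, adjusted p = 0.303 with an estimated correlation. Among 16 TGF-beta genes 0 were higher and 13 lower (0 and 14 adjusted over the list alone), camera adjusted p = 1.32e-07, adjusted p = 0.303 with an estimated correlation. Genes of dividing cells rose, among them the mitotic kinase Aurka (2.69 ± 0.23), the mitotic regulator Cdc20 (2.34 ± 0.34) and the replication licensing genes Mcm7 (2.15 ± 0.30) and Cdc6 (2.55 ± 0.33). Of 29 cell cycle genes, 24 were higher and 0 lower (25 and 1 adjusted over the list alone), camera adjusted p = 4.01e-10, adjusted p = 0.303 with an estimated correlation. The cell cycle inhibitors Cdkn2a and Cdkn2b changed by -1.97 ± 0.27 and -3.70 ± 0.30. P53 and senescence genes had 1 higher and 9 lower of 19 (1 and 9 adjusted over the list alone), camera adjusted p = 0.0149, adjusted p = 0.349 with an estimated correlation. Epithelial genes appeared, with the adhesion molecule Cdh1 at 48.8 ± 28.96 against 0.397 ± 0.490 CPM (6.82 ± 0.76), the tight junction gene Cldn3 at 9.22 ± 0.73, the keratins Krt8 and Krt6a at 5.76 ± 1.0 and 9.46 ± 1.23 and Epcam at 5.03 ± 0.70. Among 26 epithelial genes 14 were higher and 4 lower (14 and 5 adjusted over the list alone), camera adjusted p = 0.000652, adjusted p = 0.408 with an estimated correlation. Of 12 keratinocyte genes, 6 were higher and 0 lower (6 and 0 adjusted over the list alone), camera adjusted p = 0.000652, adjusted p = 0.303 with an estimated correlation. Other genes that rose were Lin28a (8.95 ± 0.58), an RNA-binding protein of stem cells, the trophoblast regulator Hand1 (8.11 ± 0.83), the neuronal tubulin Tubb3 (3.76 ± 0.65), the DNA methyltransferase Dnmt3b (2.95 ± 0.38) and the chromatin remodeller Hells (2.25 ± 0.27). Pluripotency genes were not called as a group by camera, with 5 higher and 5 lower of 30 tested, Klf2 at -5.35 ± 0.65, Nanog at 0.107 ± 0.0829 against 0.757 ± 0.0628 CPM (-2.93 ± 0.59) and Pou5f1, the endogenous Oct4 gene, at 0.916 ± 0.342 against 0.143 ± 0.202 CPM. The macrophage marker Csf1r (-5.09 ± 0.89) and the growth factor response gene Egr1 (-3.22 ± 0.64) fell too. Macrophage genes had 0 higher and 15 lower of 15 (0 and 15 adjusted over the list alone), camera adjusted p = 4.53e-06, adjusted p = 0.303 with an estimated correlation. Among 22 interferon response genes 0 were higher and 16 lower (0 and 18 adjusted over the list alone), camera adjusted p = 5.11e-05, adjusted p = 0.408 with an estimated correlation. The count of lower ones became 8 without MEF day 0 replicate 1. In all, edgeR's quasi-likelihood test (Benjamini-Hochberg) called 6773 of 15246 genes, 3147 higher and 3626 lower, and 4504 where only the groups compared entered the fit. The 31 genes given with a fold change had adjusted p up to 0.00330 in that test and separate library ranges in 31. Quantile normalization gave 3826 higher and 3206 lower. Without MEF day 0 replicate 2, Lin28a was fitted at 13.11, Krt6a at 13.62, Epcam at 9.75, Cdh1 at 9.57, Thbs1 at -8.40 and Ctgf at -8.64, and without MEF day 2 replicate 1 Krt8 was fitted at 3.34.

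On day 4 the GFP-labelled cells of MEF origin had Pou5f1 at 36.1 ± 27.9 CPM against 0.143 ± 0.202 on day 0 (7.87 ± 0.86). Nanog and Esrrb, further genes of the pluripotency network, were higher by 2.19 ± 0.38 and 2.41 ± 0.51 but only at 3.74 ± 1.21 and 1.58 ± 0.699 CPM. Lin28a reached 9.67 ± 0.58. Of 30 pluripotency genes, 14 were higher and 2 lower (14 and 2 adjusted over the list alone), camera adjusted p = 0.00429, adjusted p = 0.410 with an estimated correlation. Among epithelial genes, Cdh1 was at 8.99 ± 0.81, Epcam at 8.32 ± 0.70, Cldn3 at 10.83 ± 0.76 and Krt8 at 8.98 ± 1.13 against day 0. Epithelial genes had 22 higher and 0 lower of 26 (22 and 0 adjusted over the list alone), camera adjusted p = 3.43e-09, adjusted p = 0.410 with an estimated correlation. Krt14, a keratin of basal epidermis, was at 127 ± 52.8 CPM (9.04 ± 0.66) and Hand1 at 260.4 ± 73.4 CPM (10.26 ± 0.87). Fibroblast genes stayed down: Col1a1 at -7.24 ± 0.68, the smooth muscle actin Acta2 at -10.64 ± 1.21, Pdgfrb at -8.82 ± 0.50, Thbs1 at -11.06 ± 1.17 and the intermediate filament gene Nes at -7.14 ± 0.82. Among 33 mesenchymal genes 1 was higher and 30 lower (1 and 31 adjusted over the list alone), camera adjusted p = 1.72e-09, adjusted p = 0.410 with an estimated correlation. Of 16 TGF-beta genes, 0 were higher and 13 lower (0 and 13 adjusted over the list alone), camera adjusted p = 4.06e-06, adjusted p = 0.410 with an estimated correlation. Among growth-related genes, Cdc20 rose by 3.71 ± 0.36 and the ribosomal protein gene Rpl8 by 2.21 ± 0.34. Cell cycle genes had 22 higher and 1 lower of 29 (22 and 1 adjusted over the list alone), camera adjusted p = 1.32e-05, adjusted p = 0.410 with an estimated correlation. Among 20 ribosomal protein genes 20 were higher and 0 lower (20 and 0 adjusted over the list alone), camera adjusted p = 4.56e-07, adjusted p = 0.410 with an estimated correlation. Of 17 glycolysis genes, 9 were higher and 0 lower (9 and 0 adjusted over the list alone), camera adjusted p = 0.00429, adjusted p = 0.410 with an estimated correlation. Macrophage genes had 0 higher and 12 lower of 15 (0 and 12 adjusted over the list alone), camera adjusted p = 3.74e-05, adjusted p = 0.410 with an estimated correlation. By edgeR's quasi-likelihood test (Benjamini-Hochberg) 8997 of 15246 genes, 4253 higher and 4744 lower were called, and the 20 fold changes given for this day had adjusted p up to 0.00278 and separate library ranges in 20. Quantile normalization gave 4773 higher and 4283 lower. Without MEF day 0 replicate 2 the fit gave Pou5f1 12.33, Lin28a 13.82, Epcam 13.04, Cdh1 11.73 and Thbs1 -8.81.

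On day 8 most of the pluripotency list was up in GFP-labelled cells of MEF origin. Pou5f1 stood at 271 ± 42.1 CPM (10.77 ± 0.90 against day 0), Nanog at 96.1 ± 22.5 (6.85 ± 0.40), Esrrb at 72.04 ± 15.6 (7.90 ± 0.48) and Lin28a at 224 ± 14.4 (10.80 ± 0.59). Among 30 pluripotency genes 25 were higher and 3 lower (25 and 3 adjusted over the list alone), camera adjusted p = 2.31e-09, adjusted p = 0.187 with an estimated correlation. Epithelial and epidermal genes were at their highest means of the course in several cases, Krt8 at 2420 ± 294 CPM (10.74 ± 1.20) and Krt14 at 826 ± 217 CPM (11.73 ± 0.71), beside Cdh1 (10.26 ± 0.84) and Epcam (10.56 ± 0.73). Of 26 epithelial genes, 25 were higher and 0 lower (25 and 0 adjusted over the list alone), camera adjusted p = 1.06e-14, adjusted p = 0.187 with an estimated correlation. Keratinocyte genes had 10 higher and 0 lower of 12 (11 and 0 adjusted over the list alone), camera adjusted p = 1.09e-05, adjusted p = 0.187 with an estimated correlation. Fibroblast genes were lower throughout, for example Col1a1 (-7.93 ± 0.70), Twist1 (-9.39 ± 0.69) and Lox (-10.53 ± 1.06). Among 33 mesenchymal genes 1 was higher and 32 lower (1 and 32 adjusted over the list alone), camera adjusted p = 6.02e-13, adjusted p = 0.263 with an estimated correlation. Of 16 TGF-beta genes, 0 were higher and 15 lower (0 and 15 adjusted over the list alone), camera adjusted p = 7.34e-08, adjusted p = 0.187 with an estimated correlation. Macrophage genes had 0 higher and 14 lower of 15 (0 and 14 adjusted over the list alone), camera adjusted p = 8.07e-06, adjusted p = 0.263 with an estimated correlation. Members called lower were 9 without MEF day 0 replicate 2. Replication genes such as Mcm5 (2.84 ± 0.33) and Uhrf1 (2.25 ± 0.34), which maintains DNA methylation, rose. Among 29 cell cycle genes 26 were higher and 1 lower (26 and 1 adjusted over the list alone), camera adjusted p = 7.66e-08, adjusted p = 0.331 with an estimated correlation. The neurofilament gene Nefl rose by 7.35 ± 0.77. Testing with edgeR's quasi-likelihood method (Benjamini-Hochberg) called 8782 of 15246 genes, 4383 higher and 4399 lower, and the 17 fold changes above had adjusted p up to 0.000415 and separate library ranges in 17. Quantile normalization gave 4897 higher and 4162 lower. Without MEF day 0 replicate 2 the fit gave Pou5f1 15.23, Lin28a 14.96, Epcam 15.28 and Cdh1 13.01, and without MEF day 0 replicate 1 it gave Nefl 9.88.

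By day 12 every epithelial member tested and 25 of 30 pluripotency members were higher than in the MEFs of day 0. Esrrb had 129 ± 7.81 CPM (8.80 ± 0.49), Nanog 113 ± 20.1 (7.15 ± 0.40), Pou5f1 192 ± 30.8 (10.33 ± 0.90), Lin28a 193 ± 3.41 (10.65 ± 0.59) and Dnmt3l, a cofactor of DNA methylation in germ cells and stem cells, 36.5 ± 8.16 (7.14 ± 0.51). Of 30 pluripotency genes, 25 were higher and 0 lower (25 and 0 adjusted over the list alone), camera adjusted p = 7.98e-18, adjusted p = 0.109 with an estimated correlation. Cdh1 rose by 10.94 ± 0.85 and Epcam by 11.11 ± 0.74. Epithelial genes had 26 higher and 0 lower of 26 (26 and 0 adjusted over the list alone), camera adjusted p = 4.75e-19, adjusted p = 0.109 with an estimated correlation. Krt14 was at 9.59 ± 0.67. Among 12 keratinocyte genes 11 were higher and 0 lower (11 and 0 adjusted over the list alone), camera adjusted p = 2.21e-06, adjusted p = 0.109 with an estimated correlation. Tet1 and Tet2, enzymes that oxidise methylated DNA, rose by 3.21 ± 0.66 and 3.09 ± 0.44. Of 22 DNA methylation and chromatin genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone), camera adjusted p = 8.77e-05, adjusted p = 0.150 with an estimated correlation. Early reprogramming genes had 8 higher and 1 lower of 10 (8 and 1 adjusted over the list alone), camera adjusted p = 9.77e-06, adjusted p = 0.109 with an estimated correlation. Among 13 germline genes 7 were higher and 0 lower (8 and 0 adjusted over the list alone), camera adjusted p = 0.00678, adjusted p = 0.275 with an estimated correlation. Left higher were 4 without MEF day 12 GFP replicate 2. Fibroblast genes stayed low, with Col1a1 at -7.46 ± 0.69, Acta2 at -11.22 ± 1.24 and Twist1 at -7.07 ± 0.58. Of 33 mesenchymal genes, 0 were higher and 31 lower (1 and 31 adjusted over the list alone), camera adjusted p = 2.22e-15, adjusted p = 0.139 with an estimated correlation. The ligand gene Tgfb2 was at -6.54 ± 0.36. TGF-beta genes had 0 higher and 14 lower of 16 (0 and 16 adjusted over the list alone), camera adjusted p = 2.04e-08, adjusted p = 0.114 with an estimated correlation. Among 15 macrophage genes 0 were higher and 14 lower (1 and 14 adjusted over the list alone), camera adjusted p = 2.21e-06, adjusted p = 0.186 with an estimated correlation. The lower ones numbered 8 without MEF day 0 replicate 2. Cdkn2a and Cdkn2b were still below day 0, at -1.72 ± 0.27 and -5.02 ± 0.33. The calls of edgeR's quasi-likelihood test (Benjamini-Hochberg) numbered 7773 of 15246 genes, 4017 higher and 3756 lower, and 5131 with only the groups compared in the fit. Adjusted p reached 0.00295 among the 19 fold changes given, and library ranges were separate in 19. With only those groups in the fit, 2433 were higher and 2698 lower. Values without MEF day 0 replicate 2 were 14.79 for Pou5f1, 14.81 for Lin28a, 15.83 for Epcam and 13.68 for Cdh1.

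**Figure D1:**
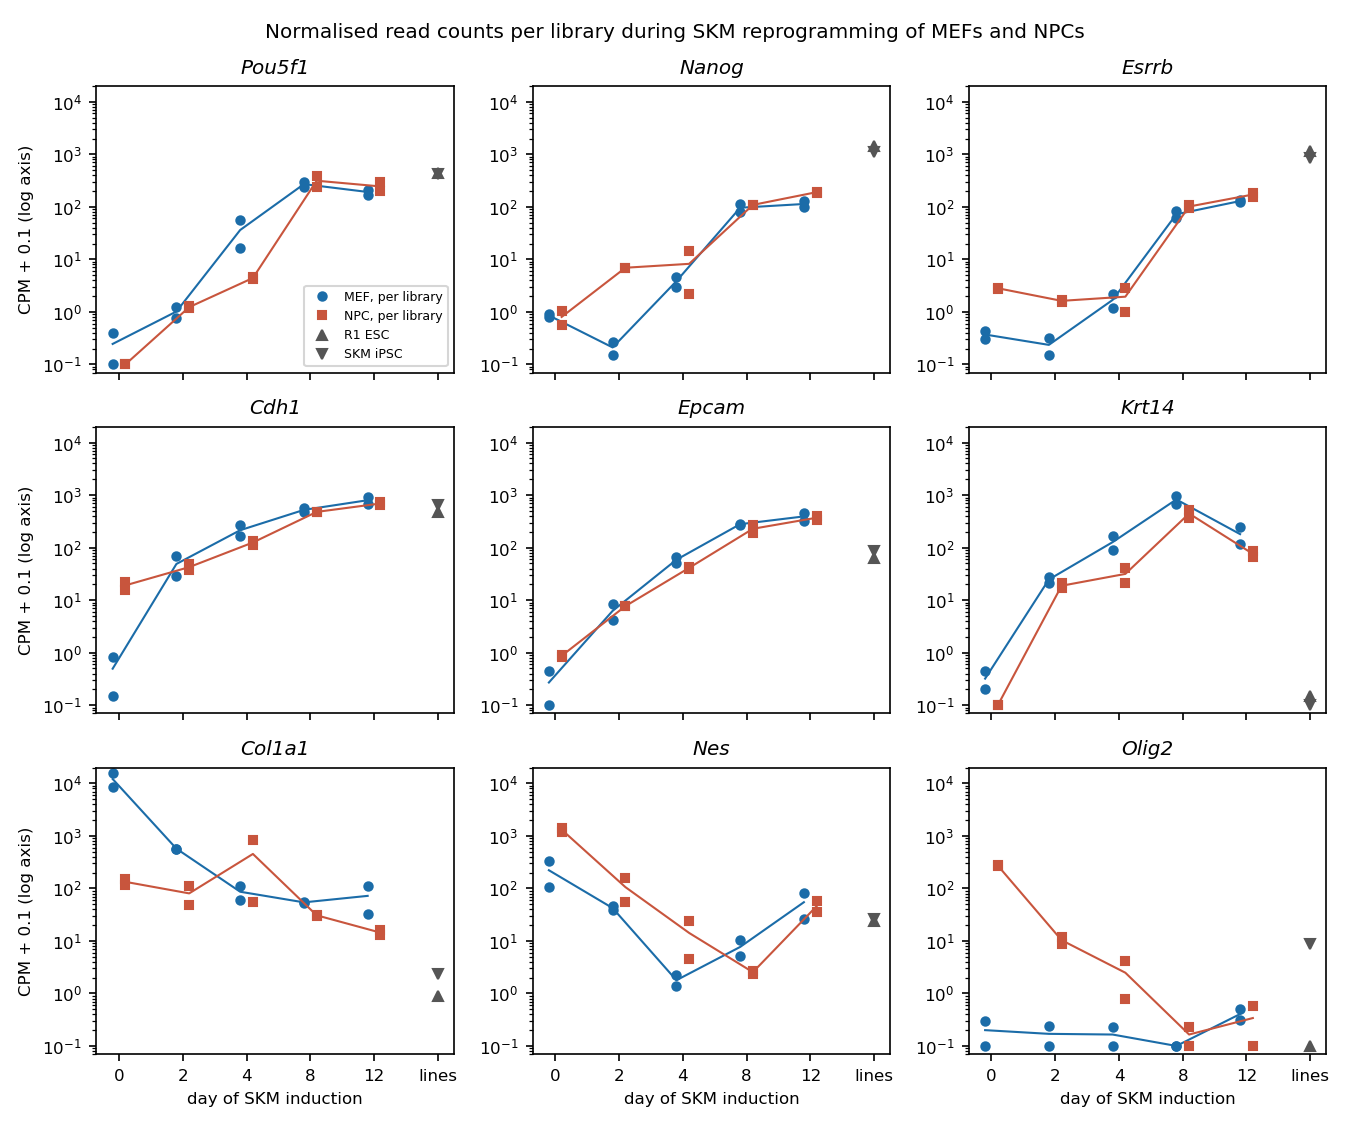
Levels of 9 genes per library on a log axis (CPM plus 0.1) against the day of SKM induction, with circles and a line of means for MEF-derived cells, squares and a line for NPC-derived cells, and triangles for the single libraries of R1 ESC and SKM iPSC. Pou5f1, Nanog, Esrrb, Cdh1 and Epcam go up in both origins, Col1a1 goes down from MEFs and Olig2 from NPCs, and Krt14 is highest on day 8.

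From day 8 to day 12 of the MEF course, pluripotency genes rose again. Dnmt3l went from 1.69 ± 0.460 to 36.5 ± 8.16 CPM (4.49 ± 0.42), and Tdgf1 (4.15 ± 0.47), Dppa4 (3.07 ± 0.42), Dppa5a (2.83 ± 0.31) and the Polycomb cofactor Jarid2 (1.94 ± 0.31) rose as well. Of 30 pluripotency genes, 16 were higher and 0 lower (21 and 0 adjusted over the list alone), camera adjusted p = 5.01e-11, adjusted p = 0.326 with an estimated correlation. The count of higher ones became 2 without MEF day 12 GFP replicate 2, 10 without MEF day 4 GFP replicate 1 or MEF day 4 GFP replicate 3 and 0 without MEF day 8 GFP replicate 1 or MEF day 8 GFP replicate 2. Tet2 rose by 2.68 ± 0.43 and the lipid carrier Apoe by 3.16 ± 0.37, while Krt14 (-2.14 ± 0.43) fell and the mitotic kinase Aurka changed by -1.37 ± 0.22. With values brought to equal quantiles, limma called 2466 genes, 1279 higher and 1187 lower. The edgeR quasi-likelihood test (Benjamini-Hochberg) called 1743 of 15246 genes, 1118 higher and 625 lower. This count rested on single libraries: 3339 without MEF day 0 replicate 1, 3374 without MEF day 0 replicate 2, 464 without MEF day 4 GFP replicate 1, 577 without MEF day 4 GFP replicate 3, 0 without MEF day 8 GFP replicate 1, 0 without MEF day 8 GFP replicate 2 and 26 without MEF day 12 GFP replicate 2. The 9 genes named had adjusted p up to 0.0246 and separate library ranges in 9, but none was called without either day 8 library, and without MEF day 12 GFP replicate 2 Dnmt3l and Apoe alone among them were called. DESeq2 called 3079 genes, and edgeR without the filter on low counts 3436.

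Day 12 cells of MEF origin were set beside R1 ESC and SKM iPSC to measure what still separated them from established lines. Most pluripotency genes lay far below the lines: Nanog by -3.44 ± 0.32, Esrrb by -2.93 ± 0.33, Zfp42 by -3.67 ± 0.39, Tdgf1 by -5.47 ± 0.46, Dppa5a by -5.67 ± 0.34 and Sall4 by -1.96 ± 0.44. As a share of the mean of the lines, Pou5f1 was at 44.4%, Nanog at 8.94%, Dppa5a at 1.91% and Lin28a at 198%. Pluripotency genes had 1 higher and 25 lower of 30 (1 and 27 adjusted over the list alone), camera adjusted p = 3.44e-17, adjusted p = 0.0733 with an estimated correlation. Germline genes such as Dazl (-7.25 ± 0.50) and Sohlh2 (-8.53 ± 0.67) were lower too. Among 13 germline genes 1 was higher and 12 lower (1 and 12 adjusted over the list alone), camera adjusted p = 2.61e-08 and adjusted p = 0.0347 with an estimated correlation. Members called lower were 4 without R1 ESC replicate 1 or SKM iPSC replicate 1. Replication genes were lower as well, with Mcm3 at -2.41 ± 0.27 and Uhrf1 at -2.19 ± 0.34. Of 29 cell cycle genes, 0 were higher and 21 lower (0 and 21 adjusted over the list alone), camera adjusted p = 7.2e-07, adjusted p = 0.385 with an estimated correlation. Left lower were 13 without MEF day 12 GFP replicate 1. Higher than in the lines were Myc (6.80 ± 0.29), Krt8 (7.07 ± 1.02), Krt19 (5.50 ± 0.57), Epcam (2.43 ± 0.46), Egr1 (9.93 ± 0.93) and Col1a1 (5.75 ± 0.67). Epithelial genes had 18 higher and 0 lower of 26 (20 and 0 adjusted over the list alone), camera adjusted p = 2.19e-07, adjusted p = 0.263 with an estimated correlation. Among 12 keratinocyte genes 11 were higher and 0 lower (11 and 0 adjusted over the list alone), camera adjusted p = 4.54e-07, adjusted p = 0.116 with an estimated correlation. Of 5 2-cell embryo genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone), camera adjusted p = 0.00886, adjusted p = 0.153 with an estimated correlation. In edgeR's quasi-likelihood test (Benjamini-Hochberg) the count was 6311 of 15246 genes, 3578 higher and 2733 lower, and 4095 without R1 ESC replicate 1, with adjusted p up to 0.00630 in the 16 named genes and separate library ranges in 16. Quantile normalization gave 3187 higher and 3425 lower.

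NPCs lost their own programme as early as day 2. The neural transcription factors Olig1 and Olig2 changed by -5.92 ± 0.86 and -4.73 ± 0.78, the lipid-binding protein Fabp7 by -6.60 ± 0.77, Nes by -3.65 ± 0.71, the matrix proteoglycan Bcan by -7.37 ± 0.71 and the astrocyte enzyme Aldh1l1 by -6.40 ± 0.71. Neural progenitor genes had 0 higher and 27 lower of 30 (0 and 27 adjusted over the list alone), camera adjusted p = 2.58e-12, adjusted p = 0.427 with an estimated correlation. Epithelial genes rose, with Cldn3 at 9.48 ± 0.58, the desmosome gene Dsp at 8.30 ± 0.52, Epcam at 3.29 ± 0.27 and the membrane protein Mal at 8.51 ± 0.89. Among 26 epithelial genes 16 were higher and 0 lower (16 and 0 adjusted over the list alone), camera adjusted p = 1.98e-08, adjusted p = 0.173 with an estimated correlation. Of 13 keratinocyte genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), camera adjusted p = 0.0124, adjusted p = 0.518 with an estimated correlation. Lin28a rose by 8.53 ± 0.46, and the neuronal genes Stmn2 and Tubb3 by 4.53 ± 0.31 and 3.49 ± 0.41. Cdh1 was at 42.4 ± 7.98 against 19.01 ± 4.49 CPM and Nanog at 6.82 ± 0.0326 against 0.703 ± 0.356 CPM. The lactate transporter Slc16a1 (2.09 ± 0.24) and the hexokinase gene Hk2 (2.12 ± 0.39) rose. Glycolysis genes had 8 higher and 0 lower of 17 (9 and 0 adjusted over the list alone), camera adjusted p = 0.00349, adjusted p = 0.518 with an estimated correlation. The higher ones numbered 2 without NPC day 0 replicate 2 and 5 without NPC day 2 replicate 1. The growth factor binding protein Igfbp3 fell (-5.71 ± 0.91), as did Egr1 (-3.79 ± 0.72). Cell cycle genes had 3 higher and 2 lower of 29 tested and were not called by camera. The edgeR quasi-likelihood test (Benjamini-Hochberg) gave 5407 of 15565 genes, 2770 higher and 2637 lower, and 2556 without NPC day 0 replicate 1, 2242 without NPC day 0 replicate 2 and 3406 without NPC day 2 replicate 1. Up to 0.00388 was reached by the adjusted p of the 20 genes with a fold change in that test, and library ranges were separate in 20. Median-of-ratios scaling gave 2408 higher and 2937 lower.

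On day 4 the NPC libraries, which carry no GFP label, were set against day 0. Olig1 (-8.37 ± 0.98), Olig2 (-6.81 ± 0.87), Fabp7 (-9.26 ± 0.88) and Nes (-6.53 ± 0.82) were lower than on day 0. Among 30 neural progenitor genes 0 were higher and 28 lower (0 and 28 adjusted over the list alone), camera adjusted p = 4.78e-13, adjusted p = 0.275 with an estimated correlation. Epcam (5.75 ± 0.29), Cdh1 (2.74 ± 0.26), Dsp (9.63 ± 0.54) and Cldn3 (10.25 ± 0.60) were higher. Of 26 epithelial genes, 23 were higher and 0 lower (23 and 0 adjusted over the list alone), camera adjusted p = 1.23e-13 and adjusted p = 0.0470 with an estimated correlation. Lin28a was at 8.23 ± 0.46 and Nanog at 3.53 ± 0.75, with 8.11 ± 8.49 CPM. The proliferation marker Mki67 (-2.63 ± 0.45) and the mitotic cyclin Ccnb2 (-2.18 ± 0.31) fell. Cell cycle genes had 2 higher and 16 lower of 29 (2 and 17 adjusted over the list alone), camera adjusted p = 0.000117, adjusted p = 0.323 with an estimated correlation. The count of lower ones became 9 without NPC day 0 replicate 1 or NPC day 0 replicate 2 or NPC day 4 replicate 2. Among 17 glycolysis genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), camera adjusted p = 0.00151, adjusted p = 0.373 with an estimated correlation. Members called higher were 4 without NPC day 0 replicate 2. The replicates differed in markers of other cells. Per the file headers, the column of replicate 1 names a feeder and that of replicate 2 none. Replicate 1 had 75.3 CPM of the macrophage gene Lyz2 against 0.189 in replicate 2, 851 against 55.3 CPM of Col1a1 and 76.1 against 7.34 CPM of Thy1. The matrix gene Dcn was higher than on day 0 (4.78 ± 0.47), at 402 and 246 CPM in replicates 1 and 2. Of 33 mesenchymal genes, 3 were higher and 4 lower with both replicates, and 2 higher and 22 lower without replicate 1. Of 6 macrophage genes, 4 were higher with both and 2 without replicate 1. Epithelial calls were 22 higher and 0 lower without it, and neural progenitor calls 0 higher and 24 lower. The edgeR quasi-likelihood test (Benjamini-Hochberg) called 6298 of 15565 genes, 3287 higher and 3011 lower, 4673 without NPC day 4 replicate 1, 3399 without NPC day 0 replicate 1 and 3214 without NPC day 0 replicate 2, and the 16 fold changes given had adjusted p up to 0.00466 and separate library ranges in 16. Median-of-ratios scaling gave 3068 higher and 3249 lower. Olig1 was at -11.73 without NPC day 4 replicate 2.

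By day 8 the GFP-labelled cells of NPC origin expressed Pou5f1 at 314 ± 111 CPM, from no counts in either day 0 library. That is at least 4625-fold higher, with the floor set at 3 counts over both day 0 libraries. Nanog rose by 7.28 ± 0.82, Esrrb by 5.24 ± 0.44 and Lin28a by 10.24 ± 0.48. Of 30 pluripotency genes, 21 were higher and 3 lower (21 and 3 adjusted over the list alone), camera adjusted p = 2.82e-06, adjusted p = 0.285 with an estimated correlation. Epcam was at 8.21 ± 0.31 and Cdh1 at 4.67 ± 0.29. Epithelial genes had 25 higher and 0 lower of 26 (25 and 0 adjusted over the list alone), camera adjusted p = 1.34e-14 and adjusted p = 0.0270 with an estimated correlation. Perp, a desmosomal target of p53, rose by 4.13 ± 0.27. Among 13 keratinocyte genes 10 were higher and 2 lower (11 and 2 adjusted over the list alone), camera adjusted p = 0.000975, adjusted p = 0.285 with an estimated correlation. The glycolytic gene Pfkl rose by 3.37 ± 0.34 and Ldha by 2.58 ± 0.35. Of 17 glycolysis genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone), camera adjusted p = 1.27e-05, adjusted p = 0.285 with an estimated correlation. Ribosomal protein genes had 20 higher and 0 lower of 20 (20 and 0 adjusted over the list alone), camera adjusted p = 7.45e-06, adjusted p = 0.609 with an estimated correlation. Lower were Nes (-9.05 ± 0.92), Pax6 (-2.40 ± 0.36), the neural cadherin Cdh2 (-9.47 ± 0.74) and Igfbp3 (-10.67 ± 1.19). Among 30 neural progenitor genes 0 were higher and 28 lower (0 and 28 adjusted over the list alone), camera adjusted p = 1.13e-12, adjusted p = 0.285 with an estimated correlation. Mki67 changed by -2.86 ± 0.46. According to edgeR's quasi-likelihood test (Benjamini-Hochberg) 9578 of 15565 genes, 4840 higher and 4738 lower were called, and the 16 fold changes given had adjusted p up to 0.000885 and separate library ranges in 16. Median-of-ratios scaling gave 4660 higher and 4909 lower. Cdh2 was at -12.29 without NPC day 8 GFP replicate 2.

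At day 12 all 30 neural progenitor genes tested were below day 0 in cells of NPC origin, with Olig2 at -10.04 ± 1.06 and Nes at -4.81 ± 0.75. Of 30 neural progenitor genes, 0 were higher and 30 lower (0 and 30 adjusted over the list alone), camera adjusted p = 2.22e-16, adjusted p = 0.245 with an estimated correlation. Pou5f1 was at 245 ± 68.3 CPM, at least 3599-fold above the floor of day 0. Nanog (8.10 ± 0.85), Esrrb (6.01 ± 0.45), Lin28a (10.32 ± 0.48) and Fbxo15 (7.87 ± 0.63) rose. Pluripotency genes had 26 higher and 0 lower of 30 (26 and 1 adjusted over the list alone), camera adjusted p = 3.04e-12, adjusted p = 0.0904 with an estimated correlation. Epcam reached 8.94 ± 0.32 and Cdh1 5.22 ± 0.30. Among 26 epithelial genes 25 were higher and 0 lower (25 and 0 adjusted over the list alone), camera adjusted p = 8.11e-18 and adjusted p = 0.0208 with an estimated correlation. Tet2 rose by 2.33 ± 0.29 and Tfap2c, a regulator of trophoblast and germ cells, by 5.56 ± 0.67. The kinase Pdk1 (3.91 ± 0.44) and the glucose transporter Slc2a1 (3.22 ± 0.31) rose. Of 17 glycolysis genes, 14 were higher and 0 lower (15 and 0 adjusted over the list alone), camera adjusted p = 3.57e-05, adjusted p = 0.245 with an estimated correlation. Mesenchymal genes that NPCs also express fell, with Vim at -7.92 ± 0.56, Cdh2 at -9.90 ± 0.75, Thy1 at -4.69 ± 0.98 and Twist1 at -5.51 ± 0.78. Mesenchymal genes had 2 higher and 24 lower of 33 (2 and 24 adjusted over the list alone), camera adjusted p = 4.63e-05, adjusted p = 0.583 with an estimated correlation. Left lower were 12 without NPC day 12 GFP replicate 1 and 14 without NPC day 12 GFP replicate 2. The count from edgeR's quasi-likelihood test (Benjamini-Hochberg) was 7409 of 15565 genes, 3750 higher and 3659 lower, and 4829 without NPC day 0 replicate 1 and 4775 without NPC day 0 replicate 2, with adjusted p up to 0.00301 in the 18 named genes and separate library ranges in 18. Median-of-ratios scaling gave 3412 higher and 3851 lower. Olig2 was at -15.35 without NPC day 12 GFP replicate 2, which left no counts in the group.

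**Figure D2:**
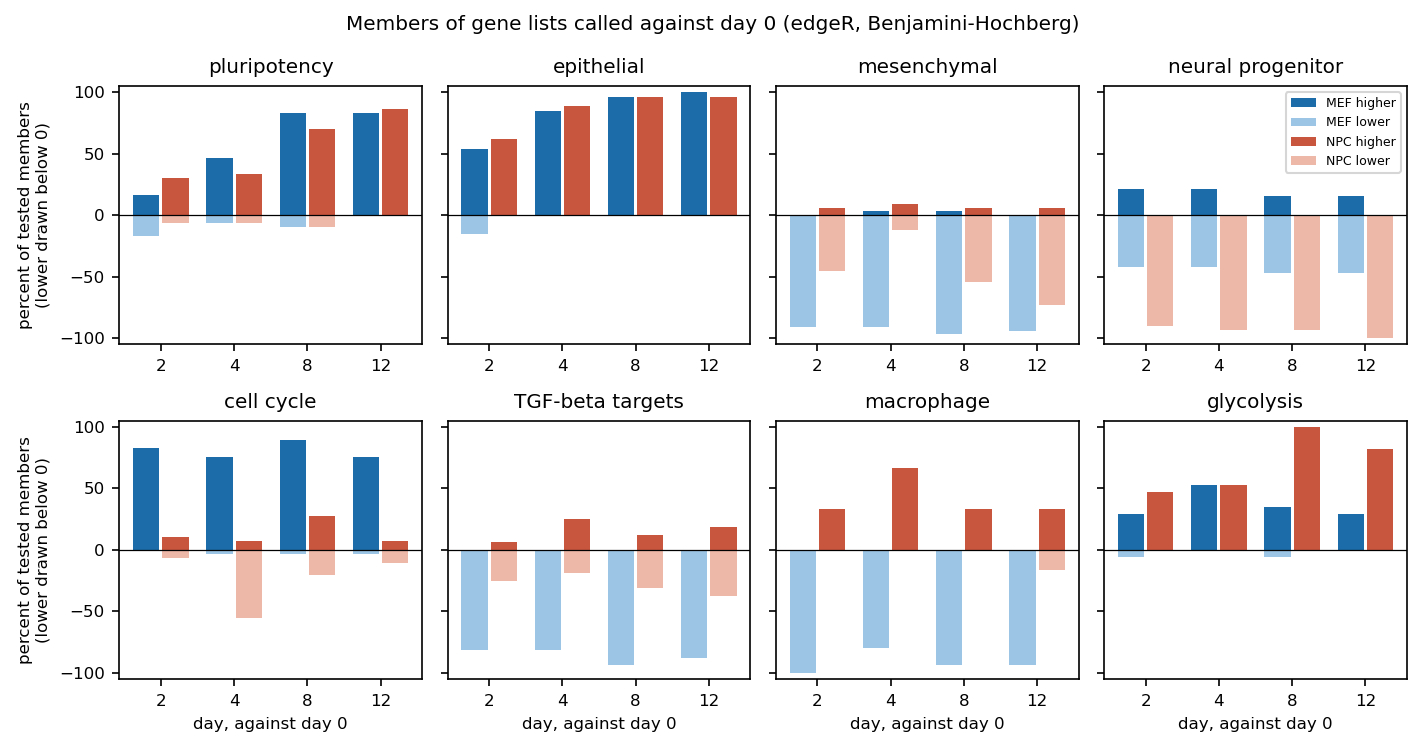
Percentage of the tested members of 8 gene lists called higher (above 0) or lower (drawn below 0) than on day 0, for days 2, 4, 8 and 12, in MEF-derived and NPC-derived cells. On days 8 and 12 most epithelial and pluripotency members are higher in both origins. Most cell cycle members are higher on each day in MEF-derived cells.

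Between days 8 and 12 of the NPC course, late pluripotency genes rose: Dnmt3l from 0.198 ± 0.188 to 9.87 ± 4.36 CPM (5.63 ± 0.75), Fgf4 by 2.85 ± 0.45, Dppa5a by 2.93 ± 0.37, Zfp42 by 2.73 ± 0.37 and Fbxo15 by 2.40 ± 0.43. Among 30 pluripotency genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone), camera adjusted p = 1.21e-06, adjusted p = 0.588 with an estimated correlation. The higher ones numbered 0 without NPC day 12 GFP replicate 2 and 11 without NPC day 8 GFP replicate 1. Tet1 and Tet2 rose by 3.50 ± 0.46 and 3.43 ± 0.31. Krt14 (-2.53 ± 0.35), Cldn3 (-2.51 ± 0.39), Hand1 (-3.30 ± 0.37) and the apoptosis gene Bbc3 (-2.59 ± 0.31) fell. Of 20 ribosomal protein genes, 0 were higher and 15 lower (0 and 19 adjusted over the list alone), camera adjusted p = 4.94e-06, adjusted p = 0.885 with an estimated correlation. The count of lower ones became 5 without NPC day 12 GFP replicate 1 and 0 without NPC day 12 GFP replicate 2 or NPC day 8 GFP replicate 1. From edgeR's quasi-likelihood test (Benjamini-Hochberg) came 4577 of 15565 genes, 2100 higher and 2477 lower, and 1673 without NPC day 8 GFP replicate 1, 2298 without NPC day 12 GFP replicate 1 and 51 without NPC day 12 GFP replicate 2, or 1753 with only the groups compared in the fit. The 11 named genes had adjusted p up to 0.00757 and separate library ranges in 11. Without NPC day 12 GFP replicate 2, Tet1 and Tet2 were the only ones of them called. Quantile normalization gave 2318 higher and 2305 lower.

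Against the pluripotent lines, day 12 cells of NPC origin were lower in Dppa5a (-7.0 ± 0.41), Tdgf1 (-7.55 ± 0.88), Zfp42 (-3.64 ± 0.37) and Esrrb (-2.54 ± 0.38). Pou5f1 lay at 56.6% of the mean of the lines, Nanog at 15.03% and Lin28a at 182%. Pluripotency genes had 1 higher and 27 lower of 30 (1 and 28 adjusted over the list alone), camera adjusted p = 2.53e-13 and adjusted p = 0.0392 with an estimated correlation. The germline genes Dazl and Sohlh2 changed by -8.96 ± 0.60 and -9.45 ± 0.64. Among 13 germline genes 1 was higher and 11 lower (1 and 11 adjusted over the list alone), camera adjusted p = 1.54e-07 and adjusted p = 0.0392 with an estimated correlation. Members called lower were 3 without R1 ESC replicate 1 or SKM iPSC replicate 1. The licensing gene Mcm3 was at -2.61 ± 0.29. Of 29 cell cycle genes, 0 were higher and 19 lower (0 and 19 adjusted over the list alone), camera adjusted p = 8.14e-06, adjusted p = 0.121 with an estimated correlation. Left lower were 10 without NPC day 12 GFP replicate 1 and 8 without NPC day 12 GFP replicate 2. Myc (6.85 ± 0.32), Egr1 (9.75 ± 1.02), Krt8 (6.58 ± 0.77) and Krt19 (5.0 ± 0.61) were higher than in the lines. Epithelial genes had 17 higher and 1 lower of 26 (18 and 1 adjusted over the list alone), camera adjusted p = 8.8e-06, adjusted p = 0.121 with an estimated correlation. Among 13 keratinocyte genes 12 were higher and 0 lower (12 and 0 adjusted over the list alone), camera adjusted p = 3.5e-06, adjusted p = 0.121 with an estimated correlation. Its count in edgeR's quasi-likelihood test (Benjamini-Hochberg) was 6173 of 15565 genes, 3324 higher and 2849 lower, and 4080 without NPC day 12 GFP replicate 1 and 3945 without NPC day 12 GFP replicate 2, with adjusted p up to 0.000717 in the 11 named genes and separate library ranges in 11.

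Before induction the 2 cell types differed as their labels say. Olig1 (-10.78 ± 1.20), Olig2 (-11.20 ± 1.18), Ncan (-10.63 ± 1.06), Fabp7 (-7.17 ± 1.04), Pax6 (-3.82 ± 0.60) and Sox2 (-5.20 ± 0.28) were lower in MEFs than in NPCs. Of 30 neural progenitor genes, 1 was higher and 28 lower (1 and 29 adjusted over the list alone), camera adjusted p = 7.24e-22 and adjusted p = 0.0132 with an estimated correlation. Neuronal genes had 1 higher and 10 lower of 12 (1 and 10 adjusted over the list alone), camera adjusted p = 2.08e-08 and adjusted p = 0.0132 with an estimated correlation. Col1a1 (6.53 ± 1.01), Snai2 (5.36 ± 1.07), Lox (8.51 ± 1.43) and Cdkn2a (1.58 ± 0.28) were higher in MEFs. Among 33 mesenchymal genes 24 were higher and 0 lower (26 and 0 adjusted over the list alone), camera adjusted p = 1.96e-09, adjusted p = 0.332 with an estimated correlation. The higher ones numbered 12 without NPC day 0 replicate 1 and 13 without NPC day 0 replicate 2. Of 16 TGF-beta genes, 14 were higher and 0 lower (14 and 0 adjusted over the list alone), camera adjusted p = 5.97e-10 and adjusted p = 0.0498 with an estimated correlation. Macrophage genes were also higher in MEF cultures, Lyz2 at 125 and 275 against 0.0903 and 0.182 CPM. Macrophage genes had 15 higher and 0 lower of 15 (15 and 0 adjusted over the list alone), camera adjusted p = 3.79e-08, adjusted p = 0.253 with an estimated correlation. Mki67 (-2.14 ± 0.44) and Uhrf1 (-2.20 ± 0.30) were lower in MEFs, and Cdh1 (-5.58 ± 0.63) and Esrrb (-3.27 ± 0.54) were lower as well. Among 29 cell cycle genes 0 were higher and 26 lower (0 and 28 adjusted over the list alone), camera adjusted p = 4.75e-12, adjusted p = 0.0970 with an estimated correlation. This comparison gave 5450 of 16188 genes, 2634 higher and 2816 lower in edgeR's quasi-likelihood test (Benjamini-Hochberg), and 3366 without NPC day 0 replicate 1 and 3211 without NPC day 0 replicate 2, with adjusted p up to 0.00192 in the 14 named genes and separate library ranges in 14. Median-of-ratios scaling gave 2783 higher and 2693 lower. Without MEF day 0 replicate 1, which left no counts of the first 3, Olig1 was fitted at -16.31, Olig2 at -15.33, Ncan at -15.31 and Fabp7 at -9.43, and without MEF day 0 replicate 2 Cdh1 at -8.34.

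Both cell types shared a large part of their response, measured over 14770 genes tested in both. On day 2, 1776 genes were higher in both against 577.3 expected for independent lists, and 1489 lower against 511.6. On day 12 these numbers were 2426 against 987.5 and 2085 against 747.5. Fold changes correlated across genes, which are not independent replicates, with r = 0.677, 0.623, 0.778 and 0.757 on days 2, 4, 8 and 12. On day 4 only MEF-derived cells were GFP-labelled, so its r compares unlike samples. A test then took the difference of the log2 fold changes, positive where the change in MEF-derived cells lay above that in NPC-derived cells. On day 2, cell cycle genes had positive differences: Mcm3 by 2.08 ± 0.38, Cdc6 by 2.11 ± 0.42 and Uhrf1 by 2.47 ± 0.42. Of 29 cell cycle genes, 20 were higher and 0 lower (26 and 0 adjusted over the list alone), camera adjusted p = 2.38e-19, adjusted p = 0.0588 with an estimated correlation. The count of higher ones became 11 without MEF day 0 replicate 2, 10 without MEF day 2 replicate 1, 13 without MEF day 2 replicate 2, 9 without NPC day 0 replicate 1 or NPC day 0 replicate 2 and 8 without NPC day 2 replicate 1. Sox2 (5.49 ± 0.35), Cdh1 (5.78 ± 0.78), the nuclear pore gene Nup210 (8.91 ± 0.48) and the receptor Fgfr3 (3.39 ± 0.51) also had positive differences. Nanog (-6.09 ± 1.21), the collagen Col5a2 (-4.55 ± 0.75), the muscle filament Des (-5.72 ± 0.66) and Krt19 (-6.16 ± 0.99) had a negative difference. Neural progenitor genes had 7 higher and 0 lower of 30 (8 and 0 adjusted over the list alone), camera adjusted p = 3.94e-07, adjusted p = 0.150 with an estimated correlation. Among 22 interferon response genes 0 were higher and 6 lower (0 and 6 adjusted over the list alone), camera adjusted p = 2.997e-06, adjusted p = 0.257 with an estimated correlation. The interaction term of edgeR's quasi-likelihood test (Benjamini-Hochberg) called 1304 of 16188 genes, 660 higher and 644 lower, and 691 without MEF day 2 replicate 1, 627 without NPC day 0 replicate 1, 570 without NPC day 0 replicate 2 and 806 without NPC day 2 replicate 2, with 748 when only the groups compared entered the fit and 2081 by DESeq2. The highest adjusted p of the 11 named genes was 0.00651 in that edgeR test. Median-of-ratios scaling gave 623 higher and 694 lower. Cdh1 was at 8.54 without MEF day 0 replicate 2.

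The responses up to day 12 were tested in the same way, and each value is the day 12 difference between the origins minus that of day 0. Of 30 neural progenitor genes, 18 were higher and 0 lower (24 and 0 adjusted over the list alone), camera adjusted p = 3.87e-15 and adjusted p = 0.0254 with an estimated correlation. Neuronal genes had 10 higher and 1 lower of 12 (10 and 1 adjusted over the list alone), camera adjusted p = 1.54e-08 and adjusted p = 0.0254 with an estimated correlation. Members called higher were 6 without MEF day 12 GFP replicate 1. Examples are the synaptic gene Syt1 (6.08 ± 0.68) and Fgfr3 (4.28 ± 0.53). Cell cycle examples are Mcm2 (2.00 ± 0.36) and Uhrf1 (2.48 ± 0.42). Among 29 cell cycle genes 17 were higher and 0 lower (24 and 0 adjusted over the list alone), camera adjusted p = 1.56e-10, adjusted p = 0.129 with an estimated correlation. Left higher were 11 without MEF day 0 replicate 2 or NPC day 0 replicate 1 or NPC day 0 replicate 2 or NPC day 12 GFP replicate 2 and 10 without NPC day 12 GFP replicate 1. Sox2 (5.18 ± 0.35), Cdh1 (5.81 ± 0.77) and Dnmt3b (3.20 ± 0.56) had positive differences, and Col5a2 (-4.82 ± 0.76), Des (-5.76 ± 0.66), Krt19 (-6.21 ± 0.96), Snai1 (-4.39 ± 0.85) and the heat shock gene Hspa1b (-3.22 ± 0.61) had negative ones. The same edgeR interaction test (Benjamini-Hochberg) called 2383 of 16188 genes, 1381 higher and 1002 lower, and 1487 without NPC day 0 replicate 1, 1379 without NPC day 0 replicate 2 and 1503 without NPC day 12 GFP replicate 1, with adjusted p up to 0.00287 in the 12 named genes. Cdh1 was at 8.56 without MEF day 0 replicate 2.

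Set side by side on day 12, GFP-labelled cells of the 2 origins gave 0 called genes of 16188 in edgeR's quasi-likelihood test (Benjamini-Hochberg), with 862 genes at an unadjusted p under 0.05. DESeq2 called 64 genes, 51 higher and 13 lower in cells of MEF origin, edgeR without the filter on low counts 166, and limma on quantile-normalised values 5. Without MEF day 12 GFP replicate 1 or 2, edgeR called 4 or 8. The DNA methyltransferase Dnmt3b was at 30.6 ± 0.170 CPM in cells of MEF origin and 7.54 ± 1.45 in cells of NPC origin (2.03 ± 0.39), Pecam1 at 15.8 ± 4.71 and 5.16 ± 0.656 (1.63 ± 0.36), and Tcl1 at 3.30 ± 0.257 and 17.7 ± 0.0348 (-2.40 ± 0.46). DESeq2 called all 3 of these, with adjusted p of 0.000246, 0.00983 and 6.5e-05. As groups, mesenchymal genes (camera adjusted p = 1.25e-09, adjusted p = 0.445 with an estimated correlation) and trophoblast genes (camera adjusted p = 2.21e-06, adjusted p = 0.115 with an estimated correlation) tended higher in cells of MEF origin. Among other lists, camera called early reprogramming genes higher (camera adjusted p = 0.0297, adjusted p = 0.278 with an estimated correlation) and ribosomal protein genes lower (camera adjusted p = 0.0172, adjusted p = 0.634 with an estimated correlation). Both calls were lost without MEF day 12 GFP replicate 2 or NPC day 12 GFP replicate 1, with adjusted p up to 0.482 and 0.832. Camera no longer called the mesenchymal list without MEF day 12 GFP replicate 1 (0.315) or the trophoblast list without MEF day 12 GFP replicate 2 (0.412).

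Astrocyte, endothelial and mesendoderm lists were called by camera in 0 of the 16 comparisons. List calls are printed here in part. Of the 155 list calls over all comparisons, 12 held with an estimated correlation: the epithelial list on days 4, 8 and 12 of the NPC course, the germline list against the lines in both origins, the pluripotency list against the lines in NPC-derived cells, the neural progenitor, neuron and early reprogramming lists in the day 12 interaction, and the neural progenitor, neuron and TGF-beta lists between the starting cells. In none of the 155 did the median, the mean and the test of a list differ in sign.

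The authors' own deposited comparisons state an adjusted p but no test. At adjusted p under 0.05 they gave, in MEF-derived cells, 693 higher and 1237 lower on day 2, 1488 and 2004 on day 4, 1589 and 2289 on day 8, and 1281 and 1669 on day 12. In NPC-derived cells they gave 872 and 1235, 1329 and 1226, 1991 and 2448, and 1624 and 2771. From day 8 to day 12 they listed 124 higher and 7 lower genes in MEF-derived cells and 110 and 87 in NPC-derived cells. The smallest log2 fold change among these calls ran from 1.46 to 2.30 in size over the comparisons, while the calls above had no such limit.

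The ChIP-seq lists of day 2 asked where Sox2 and Klf4 bind early in MEF reprogramming. The Sox2 lists held 39557 and 49209 peaks with a median fold enrichment of 5.08 and 5.43, and the Klf4 lists 6032 and 5976 peaks with 3.17 and 2.76. The deposited -log10 q was 0 for 5998 of 6013 Klf4 peaks used in replicate 1 and 5964 of 5966 in replicate 2, while its median over Sox2 peaks was 5.45 and 6.27. Of Sox2 replicate 1 peaks, 78.4% (95% confidence interval 77.97 to 78.8%) overlapped replicate 2, against 1.33% after circular shifts along the chromosomes. It was 62.96% from the side of replicate 2, and 40.5% with the 5000 peaks of lowest p per list. The Klf4 replicates shared less, with 21.3% (95% confidence interval 20.3 to 22.4%) against 0.0393%, and 9.90% with 50% reciprocal overlap. Regions found by both replicates numbered 30735 for Sox2 and 1250 for Klf4. With any overlap of at least 1 bp, most Klf4 regions of all peaks lay in Sox2 regions: 959 of 1250, or 76.7% (95% confidence interval 74.3 to 79.04%), against 0.726% after shifts, and 11.4% where 50% reciprocal overlap was asked. With the 5000 peaks of lowest p per list, which left 2024 Sox2 regions, the share was 13.2%, 135 of 1019. With all peaks it was 53.1% without Klf4 replicate 1 and 61.2% without Klf4 replicate 2. The Klf4 samples carry a Sox2 antibody label. Their peaks lay in Sox2 peaks of replicates 1 and 2 at 67.6% and 66.99% for Klf4 replicate 1, and at 58.7% and 58.3% for replicate 2. Ranked by the higher fold enrichment of the 2 replicates, the first Sox2 regions, in build mm9, were 3:129386614-129387229 (fold enrichment 5.30 and 17.2), 18:76144516-76145404 (10.1 and 15.1), 10:92332559-92333351 (8.82 and 14.9), 19:23903602-23904042 (9.62 and 14.8) and 5:8488800-8489386 (10.1 and 14.7). The first Klf4 regions by the same ranking were 9:34087517-34087798 (fold enrichment 7.72 and 5.53), 13:30460746-30460908 (7.02 and 4.93), 15:93019884-93020098 (7.02 and 3.73), 13:19682993-19683320 (4.84 and 6.43) and 10:97971226-97971541 (6.32 and 4.03). The first of these had no Sox2 region and the other 4 did. Intervals are Clopper-Pearson, and each 2-sided shift p was 0.002, the smallest that 1000 shifts can give.

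H3K27ac showed how these regions sat relative to active chromatin before and after induction. Of 42025 day 2 peaks, 50.5% (95% confidence interval 49.97 to 50.9%) overlapped a day 0 peak, against 3.45% after shifts. The share was 24.1% of the 63795 day 0 peaks, and with 50% reciprocal overlap 15.8% and 10.4%. The samples came from different lines, OG2 MEFs on day 0 and SKM secondary MEFs on day 2, with 1 library each, so the difference has no replicate check. Sox2 regions lay in day 0 peaks at 14.2% (shifted 3.20%) and in day 2 peaks at 26.4% (95% confidence interval 25.9 to 26.9%) (shifted 1.56%), with 17.2% in peaks of day 2 alone, which became 11.3% without Sox2 replicate 1. With 50% reciprocal overlap the order turned, with 1.49% in day 0 and 0.839% in day 2 peaks, 1.33% in peaks of day 0 alone and 0.787% in peaks of day 2 alone. The 5000 peaks of lowest p per list gave 1.14% (shift p of 0.016) and 4.45% for days 0 and 2. Klf4 regions lay in day 0 peaks at 42.2% (shifted 2.79%) and in day 2 peaks at 31.5% (95% confidence interval 28.95 to 34.2%) (shifted 1.26%), with 7.68% in peaks of day 2 alone. Without Klf4 replicate 1 these shares were 27.1%, 17.1% and 4.43%, and without Klf4 replicate 2 they were 31.6%, 20.3% and 4.81%. The 5000 peaks of lowest p per list gave 17.8% and 15.1% for days 0 and 2. Klf4 regions without Sox2 were in day 0 peaks at 52.9%, those with Sox2 at 38.9% and Sox2 regions without Klf4 at 13.3%, and in day 2 peaks at 39.5%, 29.1% and 25.3%. Each other shift p to this point was 0.002. With 50% reciprocal overlap, Klf4 regions in day 2 peaks fell to 0.168% with a shift p of 0.827, and in day 0 peaks to 0.336% with 0.262. Median peak widths were 71 and 65 bp for Klf4, 302 and 306 bp for Sox2 and 415 bp for H3K27ac on day 2.

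**Figure D3:**
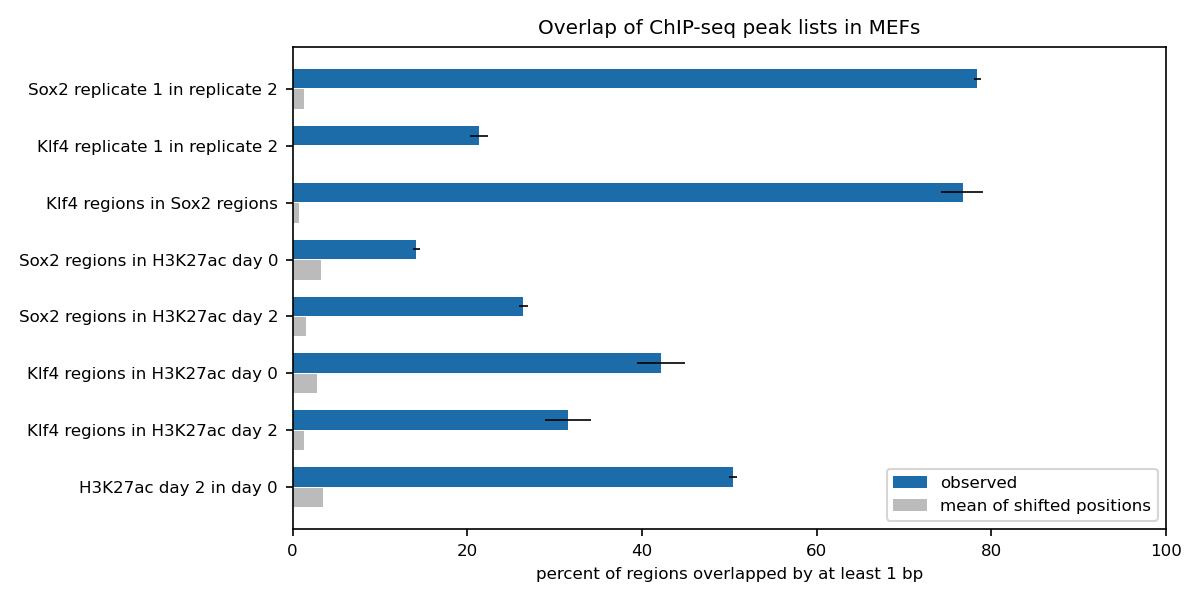
Percentage of peaks or regions overlapped by at least 1 bp (bars, with 95% Clopper-Pearson intervals) beside the mean of 1000 circular shifts (grey). Sox2 replicate overlap and Klf4 regions in Sox2 regions are the highest, at 78.4% and 76.7%.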

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

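Tests chosen only after the result was seen are both tests of the Klf4 peaks and the mixture test of the pluripotency genes.

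MEF and NPC responses differed by interaction test in 1304 genes on day 2 and 2383 on day 12. Positive values mean a larger rise or a smaller fall in MEF-derived cells. On day 2 the differences were Sox2 5.49, Cdh1 5.78, Nup210 8.91, Uhrf1 2.47, Mcm3 2.08, Cdc6 2.11, Nanog -6.09, Col5a2 -4.55, Des -5.72, Fgfr3 3.39 and Krt19 -6.16. The cell cycle (camera adjusted p = 2.38e-19), neural progenitor (3.94e-07) and interferon response (2.997e-06) lists were among those that differed. None of these 3 calls held (adjusted p = 0.0588, 0.150 and 0.257 in turn with an estimated correlation). On day 12 the differences were Sox2 5.18, Cdh1 5.81, Uhrf1 2.48, Mcm2 2.00, Col5a2 -4.82, Des -5.76, Krt19 -6.21, Fgfr3 4.28, Syt1 6.08, Snai1 -4.39, Hspa1b -3.22 and Dnmt3b 3.20. Among the lists that differed on day 12 were neural progenitor (3.87e-15), neuron (1.54e-08), early reprogramming (5.67e-05) and cell cycle (1.56e-10). The cell cycle call was lost, with adjusted p = 0.129 with an estimated correlation, and the other 3 held at 0.0254. By construction each value is the difference between the origins on that day minus their difference on day 0. Sox2 and Cdh1 differed by -5.20 and -5.58 between MEFs and NPCs on day 0 and by -0.02 and 0.22 between the day 12 groups. On day 2 Sox2 was at 819 and 668 CPM and Cdh1 at 48.8 and 42.4 CPM. The values of these 2 genes on both days thus come mostly from the starting difference. edgeR called 5450 genes on day 0 and 0 between the day 12 groups, with 862 there at an unadjusted p under 0.05 and 64 called by DESeq2. For the other genes this was not tested apart on day 2.

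NPC day 4 replicate 1, whose column heading names a feeder, stood apart from replicate 2, headed without one, in fibroblast and macrophage genes. Of 20 genes high in MEFs and low in NPCs on day 0, 14, or 70%, were at least 4 times higher in replicate 1, and 0 in replicate 2. RNA of cells like the starting MEFs is a candidate, but cannot be told apart from another change of this culture. The share expected in advance was 75%, and the pattern lies in a single library. Xist was at 27.7 CPM in replicate 1 but at 0.153 and 0.0572 CPM in the MEF day 0 libraries. Those MEFs thus do not account for it, and RNA of feeder cells, which have no library here, stays open. A culture that had lost less of its neural progenitor expression was argued against, since the median log2 ratio over 30 neural progenitor genes was -0.95.

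Klf4 peaks lay at Sox2 peaks, and the Klf4 samples carry a Sox2 antibody label. Chromatin precipitated with a Sox2 antibody might give this: the share of Klf4 peaks in Sox2 peaks was 0.862 of the share of Sox2 peaks found in the other Sox2 replicate. It cannot be told apart from binding of both factors at the same sites, because no sample carries a Klf4 antibody label. Of the strongest 1000 Sox2 regions, 8.1% held a Klf4 region, under the 50% set as what that explanation needs. Chance placement of the Klf4 peaks was argued against, as the Klf4 replicates overlapped at 143 times the highest share of the shifted lists. Background that recurs at the same sites in both replicates would also exceed the shifted lists, so it stays open.

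Pluripotency genes lay below the pluripotent lines on day 12. A simple mixture of cells at the level of the lines with cells lacking these genes was argued against, because such a mixture needs equal percentages and the highest was 104 times the lowest. The scaling of the libraries was argued against too, since at least 25 members were lower under median-of-ratios and quantile scaling in both origins. Incomplete reprogramming and differences between cultures and established lines stay open as untested.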

How the results depend on the processing

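Tests chosen only after the result was seen are those with DESeq2, gene lists with each library left out, and lists without NPC day 4 replicate 1. The cause of the changes given here was not tested. With only the groups compared in the fit, calls were 4504 on MEF day 2, 5131 on MEF day 12, 1753 from day 8 to day 12 of the NPC course and 748 in the day 2 interaction. DESeq2 called 3079 from day 8 to day 12 of the MEF course, 2081 in the day 2 interaction and 64 between the day 12 groups. Without the filter on low counts there were 3436 from MEF day 8 to day 12 and 166 between the day 12 groups, and quantile normalization gave 5 there. The estimated correlation left 12 of 155 list calls. Klf4 regions in H3K27ac of day 2 fell to 0.168% with 50% reciprocal overlap.

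With 1 library left out, where the lone sample of a group is assumed to vary like the other groups, calls ran from 0 to 3374 for MEF day 12 against day 8, 4095 to 7358 for MEF day 12 against the lines, 2242 to 6317 for NPC day 2, 3214 to 7259 for NPC day 4, 4775 to 8237 for NPC day 12, 51 to 5725 for NPC day 12 against day 8 and 3945 to 7045 for NPC day 12 against the lines. They ran from 570 to 1839 for the day 2 interaction, 1379 to 3020 for the day 12 interaction, 3211 to 5856 between the starting cells and 0 to 8 between the day 12 groups. Of 232 such counts, 201 lay within 1.5 times the count with all libraries. The ribosomal protein list between the day 12 groups turned direction without NPC day 12 GFP replicate 1 (0.8319), with camera adjusted p from 6.716e-06 to 0.8319 over the libraries left out.

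The genes printed were picked in part for steady calls, so their own counts overstate stability. Over the whole rule, 942 of 1377 called pairs of gene and comparison, 68.4%, were called with every library left out, from 0 of 53 for MEF day 12 against day 8 and 4 of 75 for NPC day 12 against day 8 to 95 of 103 for NPC day 8. Of 2296 list tests with a library left out, 2204 kept their side of the threshold and direction, 91 lost the call and 1 turned. fry kept 128 of 155 calls and the replicate block 146. The 9 calls the block ended were neuron and oligodendrocyte on MEF day 8 (camera adjusted p = 0.0520 and 0.0539 with the block), DNA methylation and chromatin from MEF day 8 to day 12 (0.0640), oligodendrocyte on NPC day 2 (0.0702), pluripotency and trophoblast on NPC day 4 (0.0766 and 0.0636), 2-cell embryo for NPC day 12 against the lines (0.137), skeletal muscle between the starting cells (0.0578) and early reprogramming between the day 12 groups (0.0661). With the replicate block, 6891 genes were called on MEF day 2 against 6773 without it, 1564 against 1304 in the day 2 interaction and 2757 against 2383 in the day 12 interaction, and all 16 counts lay within 1.5 times. Correlations of replicate differences between groups ran from -0.126 to 0.599, the highest between MEF and NPC day 2. The labels name no shared animal, batch or day behind the numbers, and with 2 replicates per group the numbers were not taken as pairs.

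Median-of-ratios scaling, no trend and a log2 fold change of at least 1 moved 0 of 16 counts by over 1.5 times. Quantile normalization shifted the median of all genes by 0.164, 0.186 and 0.122 on MEF days 2, 4 and 8, by -0.179 against the lines and by -0.145 in the day 12 interaction. Median-of-ratios scaling and DESeq2 shifted NPC day 2 by -0.110 and -0.111, and no filter shifted NPC days 8 and 12 by -0.121 and -0.101. In 12 of 15 comparisons with calls, at least 1 of 8 alternatives turned which of higher and lower was larger. Of peak overlaps, 11 of 15 had a shift p under 0.05 with reciprocal overlap, 14 of 15 with the 5000 peaks of lowest p and 8 of 8 at -log10 q of at least 5. This p does not measure the share, which for Klf4 regions in Sox2 regions went from 76.7% to 11.4% and 13.2% in the first 2 of these. Not run were a pseudocount of 0.1, because the tables hold counts, Klf4 peaks at -log10 q of at least 5, because 0 reach it, and binding near genes, because mm9 gene coordinates were not used here.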

Other observations

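Sex-linked transcripts differed between libraries. Xist was at 14.9 and 21.6 CPM in MEF day 12 GFP libraries, 0.153 and 0.0572 CPM on day 0, and 1.93 and 4.82 CPM in NPC day 12 GFP libraries. The Y-linked gene Ddx3y was present in the same day 12 libraries, at 60.9 and 130.4 CPM in MEF-derived and 102 and 139.5 CPM in NPC-derived cells.

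The MEF day 0 replicates differed in matrix and imprinted genes. H19 was at 21970.0 and 629.7 CPM, Col3a1 at 8596 and 1552 CPM and Postn at 671 and 87.2 CPM in replicates 1 and 2. Dcn stayed above day 0 in day 12 cells, at 159 and 101 against 66.4 and 6.87 CPM, while Col3a1 was at 145 and 1.96 CPM on day 12.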
